A study of Mus musculus with 9 samples.

How the data were processed

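Genomic DNA of 9 mouse mammary tumours was compared with pooled tail DNA on Agilent tiling arrays of design 027414, 1 array per tumour, with tumour DNA in the red channel and pool DNA in the green channel. There were no dye swaps and no arrays of control DNA, so each tumour is compared with the pool through its ratio, and the spread of control DNA is not part of any test. The labels give MMTV-Cre nulliparous (1), MMTV-Cre parous (1), MMTV-Cre transplant (5) and Ad-Cre transplant (2). Replicate numbers follow the order of deposit and pair no samples. The labels also mention tumours lacking p53 alone, of which none is among the samples.

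The authors scanned the arrays with Agilent Feature Extraction 10.5.1.1. The deposited processed signals are spot intensity values of each channel after background subtraction, detrending and linear dye normalisation, and the deposited median signals are raw spot and local background intensity. The authors' ratios are log10 values of red over green, and the deposited series table holds the same log10 ratios rounded. Of 974016 spots per array, 967261 were probes. The median processed reference signal was 1068 to 1147 and the median tumour signal 1067 to 1157. The files name no genome build, and the given gene table (GRCm38.p6) does not share their positions, since probes of 10 chromosomes lie beyond its last gene. It was used for names and chromosome membership alone. This number of arrays sets the precision of the means.

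The log2 ratio of the processed signals was computed for each probe. Spots not well above background in the reference channel were left out, as were spots flagged as non-uniform or population outliers in either channel. Together these were between 1597 and 2115 per array. Each array was centred on its autosomal median. The noise of single probes was between 0.16 and 0.18 on the log2 scale. Autosomal probes were taken in bins of 5 and segmented with a penalised least-squares method (PELT, penalty factor 10, at least 2 bins). Segments of at least 0.25 were called gained and of -0.25 or less lost, steps of 0.2 or more were breakpoints, and segments of at most 10 Mb at 1 or more, or -1 or less, were high-level focal events, merged within 1 Mb. In simulated data the segmentation found 100% of shifts of 0.25 over 600 probes and of 2 over 10 probes, with 0 false segments. The simulated probe noise was independent and normal, without the probe patterns that the real arrays share. The rate of false segments in the real arrays was therefore not measured.

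Tests were fixed before the data were examined, with changes the files forced. Because no probe is paired with a gene, 100 kb windows with at least 3 probes replaced genes, and gene lists were tested on chromosome values against 10000 random lists of coding genes in place of a shift along the genome. Members of a list are therefore named by chromosome, as examples picked after the chromosome values were seen. Windows were tested with limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. On simulated shifts against the pool limma recovered 72% of windows at 0.25 and 99% at 0.5 with 13 false calls, and for Ad-Cre against MMTV-Cre 35% at 0.5 and 96% at 1 with 5 false calls. These windows were simulated independently of each other, while real windows of a chromosome move together. Chromosome medians were tested against 0 with an exact two-sided sign-flip permutation (512 patterns), and groups with exact two-sided permutation tests over 36 or 21 groupings, whose smallest p are 0.0278 and 0.0476. Recurrence levels came from 10000 circular shifts. Windows were named by a rule: among those past the threshold with one sign in 9 of 9 tumours, the 10 with the largest positive and the 10 with the largest negative mean, at most 1 per 10 Mb. For transplants the window past the threshold was named.

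The target run was found as follows. The region of chromosome 11 was looked at first because the position of Trp53 was already known, and a scan of all chromosomes for runs of 4 probes at least 0.5 below their surroundings in 7 or more tumours was set after its values had been seen. The run was compared with 20 probes on each side. The planned lookup of probes inside Trp53 and Rb1 was not possible without the build.

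Alternatives were a normexp correction (offset 50) of the median signals, used because the files hold no mean signals, within-array loess, centring on the mode, the series table, other filters on dim spots, other segmentation, window and threshold settings, subsets of tumours, hybridisation day as a random block or a single day, and each tumour left out in turn. Segment size limits were added after seeing the data. A correction for GC content was planned and not run, since no genome was given. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, statsmodels 0.14.6 and matplotlib 3.10.9 were used.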

Results

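DNA copy number was measured in 9 mouse mammary tumours from models that, per the labels, carry floxed Rb and p53 alleles for removal by Cre recombinase. The tests treat these tumours as independent, and whether any transplants shared a donor was not examined. Tumour DNA carried Cy5 and was hybridised together with Cy3-labelled DNA pooled from tails of tumour-free mice on a 2-colour genome tiling array. Cre came from the MMTV promoter, which is active in mammary epithelium, in 7 tumours, and from an adenovirus (Ad-Cre) in 2. The MMTV-Cre tumours were 1 from a nulliparous mouse, 1 from a parous mouse and 5 labelled as transplants, and both Ad-Cre tumours were also labelled as transplants. Each array held 963261 distinct probes, 914119 of them on the autosomes, with a median autosomal spacing of 1782 bp. The median reference signal was between 21.8 and 32.4 times its local background and the median tumour signal between 14.9 and 17.9 times, and the number of arrays limits the precision of every mean. Values are log2 ratios of tumour to reference, centred on the autosomal median of each array, and positions are those printed in the deposited files, which name no genome build.

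The first question was whether the Cre-deleted genes could be seen as lost. On chromosome 11, the chromosome of Trp53, which encodes p53, a run of 4 probes from 69397121 to 69402566 lay below its flanks by a mean log2 ratio of -1.25 ± 0.56 (SD, n = 9). The planned exact two-sided sign-flip permutation gave p = 0.0039, but the run was picked for being low in these same tumours, so this p restates the selection. The signal left in the run was 30.8% of its flanks in the nulliparous tumour, 30.6% in the parous tumour, and 30.4%, 40.0%, 36.2% and 50.5% in MMTV-Cre transplants 1, 3, 4 and 5. It was 34.6% and 58.6% in Ad-Cre transplants 1 and 2. The library labelled MMTV-Cre transplant 2 stood apart, with 96.7% of the flank signal and a difference of -0.05. Without the library labelled MMTV-Cre transplant 2 the mean was -1.40 ± 0.35 (SD, n = 8). The run is taken here as the Cre-deleted part of Trp53 because it was the only run of 4 probes that low in at least 7 tumours, but the files pair no probe with a gene and the place was first looked at because the position of Trp53 was already known. For Rb1, the retinoblastoma gene on chromosome 14, no deleted part was identified. A run of 3 probes on chromosome 14 from 55991927 to 56000958 was low in 9 of 9 tumours and was not assigned to a gene. Nothing here ties it to Rb1. Its highest probe was at -0.96 to -0.62 relative to the surroundings, with the library labelled MMTV-Cre transplant 2 low as well. A scan for such runs of 3 probes found 6, on chromosomes 2, 7, 11, 13 and 14.

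**Figure D1:**
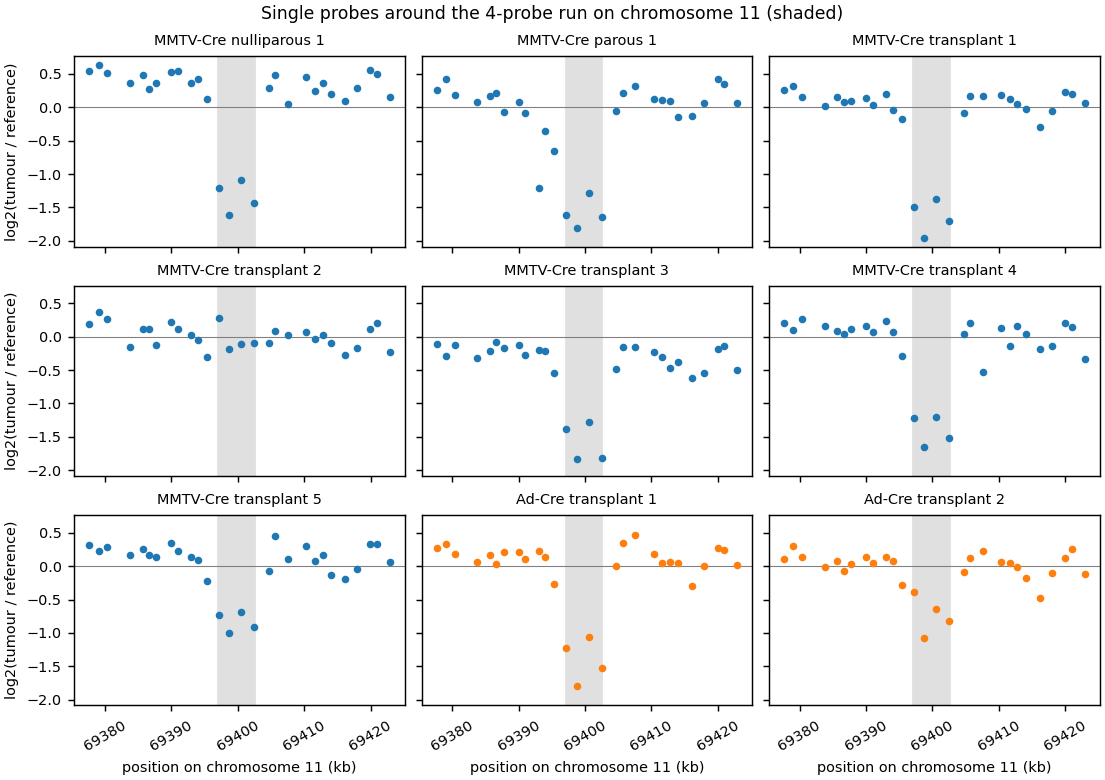
Log2 ratio of tumour to reference (y axis) of single probes along chromosome 11 (x axis, kb), 1 panel per tumour, MMTV-Cre in blue and Ad-Cre in orange, with the 4-probe run shaded. The run lies 0.77 or more below its flanks in 8 tumours and level with them in the library labelled MMTV-Cre transplant 2, where the difference is -0.05.

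The stated purpose of the series is to find alterations shared by tumours lacking Rb and p53, which the ratio against 0 addresses chromosome by chromosome. Chromosome 3 had the highest mean, 0.25 ± 0.21 (SD, n = 9), was above 0 in 9 of 9 tumours and reached 0.25 in 5 of them. It carries Pik3ca, the catalytic subunit of a growth-signalling lipid kinase, Sox2, Mcl1 and Nras. Chromosome 15, the chromosome of the oncogene Myc and of Skp2, had a mean of 0.18 ± 0.13, and chromosome 5, which carries the cell-cycle kinase Cdk6 and the DNA repair gene Brca2, 0.16 ± 0.12, each above 0 in 9 of 9 tumours. Chromosome 7, with the cyclin genes Ccnd1 and Ccne1, Fgfr2 and Igf1r, had a mean of -0.15 ± 0.11 and was below 0 in 9 of 9, and chromosome 2, with Aurka and E2f1, had a mean of -0.14 ± 0.14 and was below 0 in 8 of 9. The adjusted exact sign-flip p was 0.0186 for chromosomes 3, 5, 7 and 15 and 0.0297 for chromosome 2. Chromosome 8 followed at 0.14 ± 0.14 (adjusted exact p = 0.0742). Without the library labelled MMTV-Cre transplant 2, chromosome 8 (0.17 ± 0.12, SD, n = 8) and chromosome 4 (0.07 ± 0.08) passed as well, each above 0 in 8 of 8 tumours (adjusted exact p = 0.0247). That library had the highest value of all tumours on chromosomes 3, 5 and 15, at 0.75, 0.40 and 0.43. Without it their means were 0.19 ± 0.11, 0.14 ± 0.09 and 0.15 ± 0.09 (SD, n = 8). Each still passed (adjusted exact sign-flip p = 0.0247). The call on chromosome 2 was lost (adjusted exact p = 0.0594) when the nulliparous tumour, MMTV-Cre transplant 1, 4 or 5, or Ad-Cre transplant 1 was left out. Ad-Cre transplant 2 contributed little to these means, at 0.01 on chromosomes 3 and 5, 0.02 on chromosome 15 and -0.05 on chromosome 7. Centred on the mode of the array, its values on chromosomes 3 and 5 fall below 0.

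**Figure D2:**
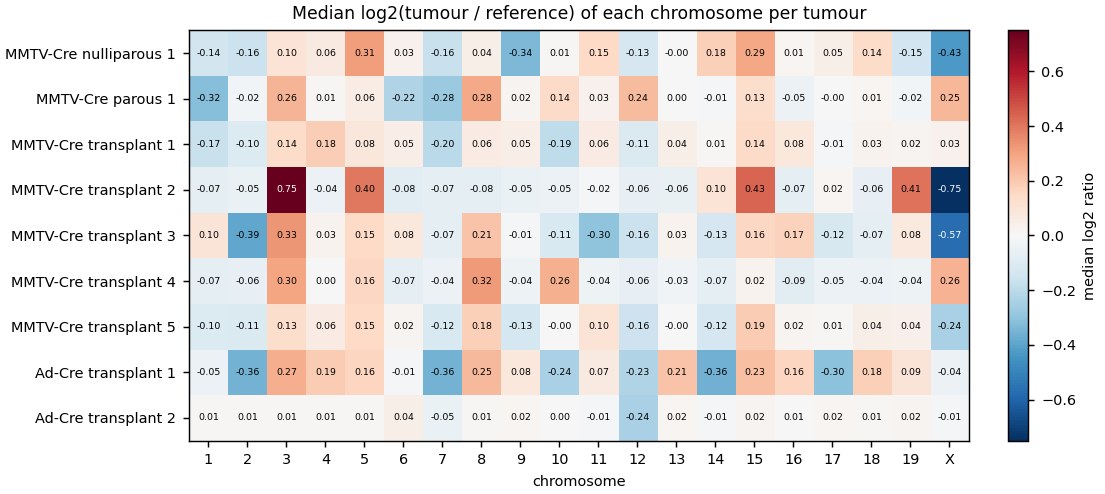
Median log2 ratio of tumour to reference of each chromosome (columns) in each tumour (rows), as colour and printed value. Chromosome 3 is above 0 in 9 of 9 tumours, from 0.01 to 0.75, and chromosome 7 is below 0 in 9 of 9.

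Along the chromosomes, 100 kb windows were tested against the pool with limma. Of 23357 windows, 3982 were gained and 4617 lost at an adjusted p under 0.05. Of 100 sign patterns of the arrays, the real one included, the other patterns gave at most 6315 called windows (median 0) against the real 8599, since windows of a chromosome move together. Gains covered 77.6% of the windows of chromosome 3, 71.1% of chromosome 15, 65.2% of chromosome 5 and 40.3% of chromosome 8. Losses covered 82.4% of chromosome 7, 66.8% of chromosome 2, 43.5% of chromosome 1 and 39.6% of chromosome 12. The share of gains among the called windows was 46.3%, and it was 64.3% with a normexp background correction and 34.1% with the arrays centred on the mode. In 3713 windows (15.9%) the 9 tumours had the same sign, but all 9 ratios share the pool and the dye orientation, and probe residuals correlated from 0.463 to 0.871 over the 36 pairs of arrays, so part of this sharing need not come from the tumours.

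Of the windows with one sign in 9 of 9 tumours, those with the largest means on chromosome 3 began at 49100001 (0.58 ± 0.09, SE), 15800001 (0.58 ± 0.09) and 94500001 (0.56 ± 0.08). On chromosome 8 the window at 76500001 had a mean of 0.59. The largest means of all belonged to short stretches, at 112000001 on chromosome 4 (1.83 ± 0.42), 105100001 on chromosome 12 (1.49 ± 0.34) and 105100001 on chromosome 5 (1.24 ± 0.20). Windows at 68600001 on chromosome 13 (1.01), 70500001 on chromosome 6 (0.85) and 53900001 on chromosome 14 (0.79) followed. By segments, no window was gained in more than 1 tumour on chromosome 13 or in more than 4 on chromosome 5. On chromosome 14 the only windows gained in 6 tumours lay from 69900001 to 70100000. The means on chromosomes 5, 13 and 14 are therefore not gains called in 9 tumours. The windows on chromosomes 4, 6 and 12 lie in short loci where the high probes had little signal in the reference channel, 0.05, 0.20 and 0.08 of the autosomal median. Among the lowest means, chromosome 7 had windows at 67700001 (-0.81 ± 0.10), 54800001 (-0.59), 26800001 (-0.55), 38900001 (-0.48) and 92600001 (-0.32). Chromosome 17 at 40100001 had -0.49, and chromosome 2 had -0.37, -0.36, -0.33 and -0.33 at 47100001, 58000001, 82500001 and 97800001. Some of these lowest windows also sit on short loci. On chromosome 7, that at 38900001 holds a high-level loss of 6 tumours. That at 26800001 lies in one of MMTV-Cre transplant 4 and the library labelled MMTV-Cre transplant 2. The window after 54800001 was gained in 6 tumours. The chromosome 17 window overlaps a short loss in the library labelled MMTV-Cre transplant 2. Which genes lie in these windows was not determined here.

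Recurrence was counted from segments called gained at 0.25 or lost at -0.25. Gains in 4 or more tumours covered 68.3% of the windows of chromosome 3, 33.6% of chromosome 8 and 30.9% of chromosome 15. The levels were set at gain in 6 tumours and loss in 5, which a proportion of 0.0223 and 0.0348 of 10000 circular shifts of each tumour along the genome reached anywhere. At these levels there were 45 gained windows and 3 lost ones. The counts depended on the settings, with 328 gained under the normexp correction and 133 with penalty factor 20. Penalty factor 5 gave 107 gained and 7 lost, and a threshold of 0.15 gave 3 gained and 55 lost. Chromosome 8 was gained in 6 tumours from 71200001 to 72500000 and from 74400001 to 75200000. The means over all 9 tumours, gained or not, were 0.32 and 0.24. The 6 gained tumours were the parous tumour, MMTV-Cre transplants 1, 3, 4 and 5 and Ad-Cre transplant 1. The lost windows were on chromosome 2 from 77700001 to 77900000 and on chromosome 16 from 35500001 to 35600000. With segments of at least 1 Mb alone, a choice made after seeing the data, 18 gained windows and 0 lost ones were at the levels. The 45 fell to 5 without MMTV-Cre transplant 1 or 4, 6 without transplant 3, 7 without transplant 5 or Ad-Cre transplant 1, 22 without the parous tumour and 24 without Ad-Cre transplant 2.

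**Figure D3:**
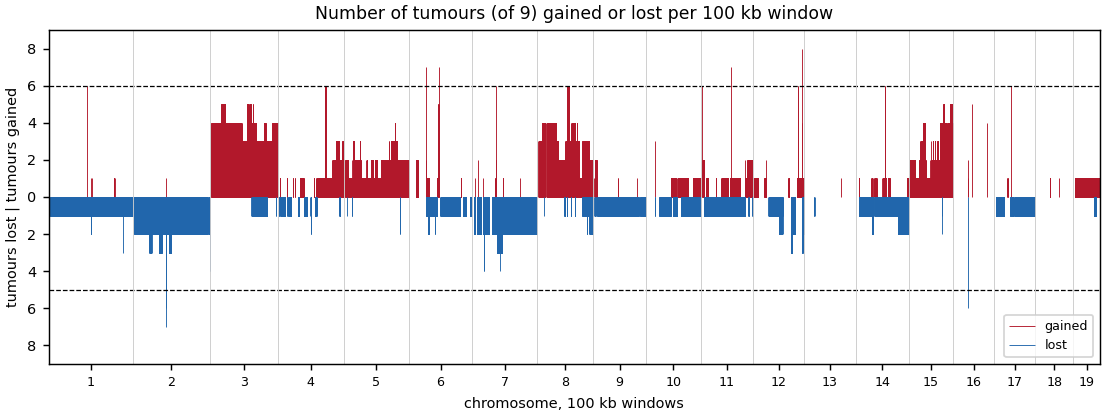
Number of tumours, of 9, gained (red, upwards) or lost (blue, downwards) in each 100 kb window along the autosomes, with dashed lines at the levels of 6 gains and 5 losses. Broad gains in 4 or more tumours are on chromosomes 3, 8 and 15, and most windows past the dashed lines are short loci.

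High-level focal events differed between tumours. The nulliparous tumour carried an amplification on chromosome 9 from 3850555 to 9376740, with a mean of 4.44 over its high segments (21.7-fold), and MMTV-Cre transplant 5 carried one from 6484696 to 9192736 with a mean of 3.47 (11.1-fold). Chromosome 9 holds Yap1, a growth-promoting transcriptional coactivator, and the apoptosis inhibitors Birc2 and Birc3. The parous tumour was amplified on chromosome 6, the chromosome of the receptor kinase Met, from 17123977 to 21003351 (4.37, 20.7-fold), and Ad-Cre transplant 2 from 17332410 to 18003972 (3.44, 10.8-fold) and from 21233642 to 21677879 (1.61). On chromosome 15 the parous tumour had amplifications from 61046355 to 62787015 (3.14, 8.83-fold), from 67375633 to 69235886 (1.68) and from 100530486 to 101301819 (2.01). MMTV-Cre transplant 1 had 8 events on chromosome 8 between 17527034 and 88995950, the weakest with a mean of 1.03 (2.04-fold) and the strongest at 2.83-fold. MMTV-Cre transplant 3 had the longest event, on chromosome 11 from 109197206 to 120749871, with a mean of 1.11 over its high segments (2.16-fold) and an extreme of 3.57-fold. It counts as overlapping in 4 tumours through short loci inside it, since the median over the interval was 0.09, 0.46 and 0.18 in MMTV-Cre transplant 1, the library labelled MMTV-Cre transplant 2 and MMTV-Cre transplant 5. Which of the named genes lie inside these intervals was not determined here, since the build of the positions is not given. In all there were 117 events, 97 gains and 20 losses, of which 58 overlapped in 4 or more tumours. Apart from the event on chromosome 11, the 16 above were those in 1 to 3 tumours of at least 300 kb, a selection made after seeing the data.

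**Figure D4:**
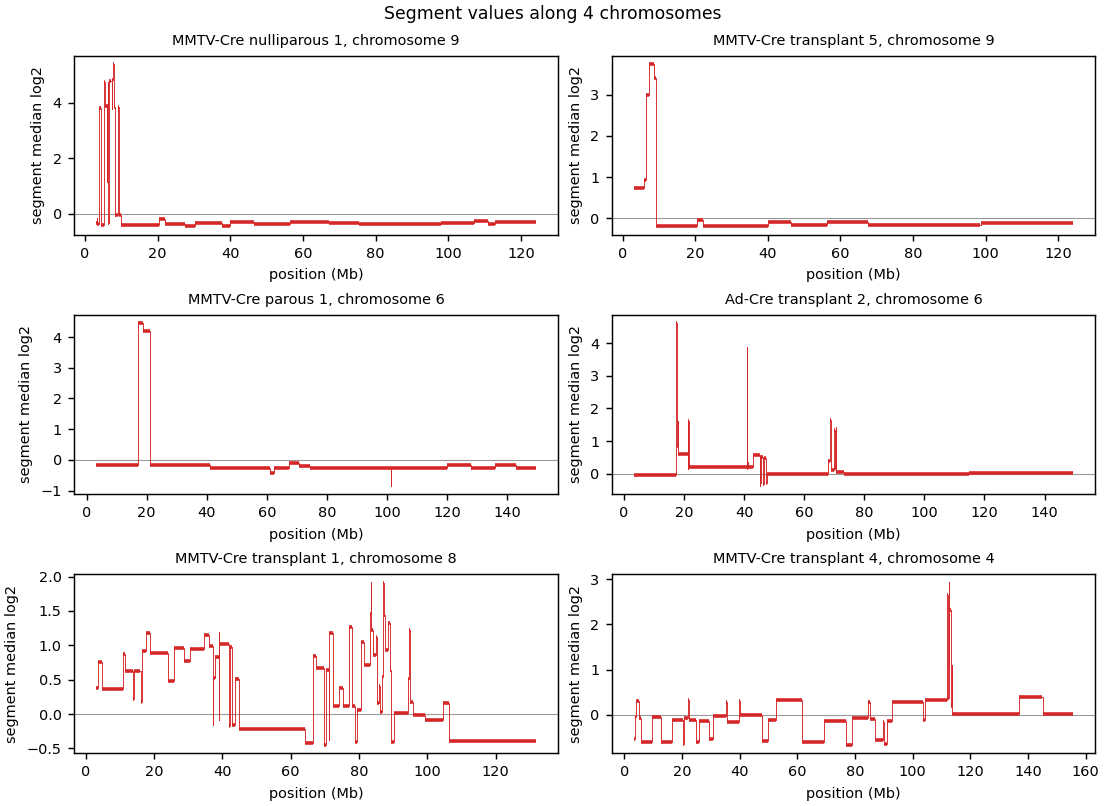
Segment median log2 ratio of tumour to reference (y axis) against position in Mb (x axis) for 6 tumours on chromosomes 9, 6, 8 and 4. The amplifications on chromosomes 9 and 6 rise above 3, and chromosome 8 of MMTV-Cre transplant 1 and chromosome 4 of MMTV-Cre transplant 4 step many times between levels; the tall narrow peak on chromosome 4 is a short shared locus.

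Breakpoints were crowded on single chromosomes. MMTV-Cre transplant 1 had 61 of its 122 breakpoints on chromosome 8, and MMTV-Cre transplant 4 had 46 of 93 on chromosome 4. The parous tumour had 21 of 49 on chromosome 15, MMTV-Cre transplant 3 had 29 of 74 on chromosome 11, the nulliparous tumour 24 of 68 on chromosome 9 and Ad-Cre transplant 2 had 28 of 108 on chromosome 6. Against 10000 random placements by probe number, a test added after seeing the data, the fullest chromosome held more than chance in 8 of 9 tumours (permutation p under 0.05), and in the library labelled MMTV-Cre transplant 2 it did not (10 of 62 on chromosome 6, permutation p = 0.0736). Steps at the short loci feed these counts. With the segments in short shared loci left out, 8 of 9 tumours again passed, with 38 of 67 breakpoints on chromosome 4 in MMTV-Cre transplant 4 and 61 of 93 on chromosome 8 in MMTV-Cre transplant 1, while the fullest chromosome of Ad-Cre transplant 1 changed from 4 (17 of 80) to 3 (12 of 48).

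The share of the autosomal length gained or lost ranged from 2.62% in MMTV-Cre transplant 5 to 38.1% in Ad-Cre transplant 1, with a mean of 16.6% ± 11.6 (SD, n = 9). The mean was 27.9% with the normexp correction, 34.4% with a gain and loss threshold of 0.15 and 3.94% with one of 0.4. It was 2.90% in Ad-Cre transplant 2, 25.8% in the parous and 17.5% in the nulliparous tumour, and 5.47% and 16.2% in MMTV-Cre transplants 1 and 4. MMTV-Cre transplant 3 had 7.51% gained and 11.5% lost. The library labelled MMTV-Cre transplant 2 had 21.6%, nearly all of it gain. A fixed threshold can miss changes damped by few tumour cells, and tumour cell content was not measured. Most signal in the chromosome 11 run, that library aside, remained in MMTV-Cre transplant 5 (50.5%) and Ad-Cre transplant 2 (58.6%). Their shares were the lowest. MMTV-Cre transplant 1 also had a low share, with 30.4% remaining. The shares and their group differences may thus partly reflect tumour cell content. The tumours had 82.7 ± 22.9 breakpoints (SD, n = 9). That mean was 53 with the normexp correction, 140 with no filter on dim spots, and 131 and 56.4 with penalty factors 5 and 20. Ad-Cre tumours averaged 20.5% and MMTV-Cre tumours 15.5%, a difference of 5.03 percentage points within the spread of the tumours (exact permutation p = 0.694; smallest possible 0.0278). The difference was 22.6 without Ad-Cre transplant 2, 2.89 without MMTV-Cre transplant 5 and 10.53 with the normexp correction, and it turned to -12.6 without Ad-Cre transplant 1 and to -1.16 within the single hybridisation day that held both models. Among MMTV-Cre tumours, transplants averaged 12.99% and the others 21.7%, a difference of -8.66 (exact permutation p = 0.190; smallest possible 0.0476). That difference was -4.56 without the parous tumour, -16.3 with the normexp correction, -11.3 (exact p = 0.0476) with a threshold of 0.15 and 3.71 with 0.4.

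**Figure D5:**
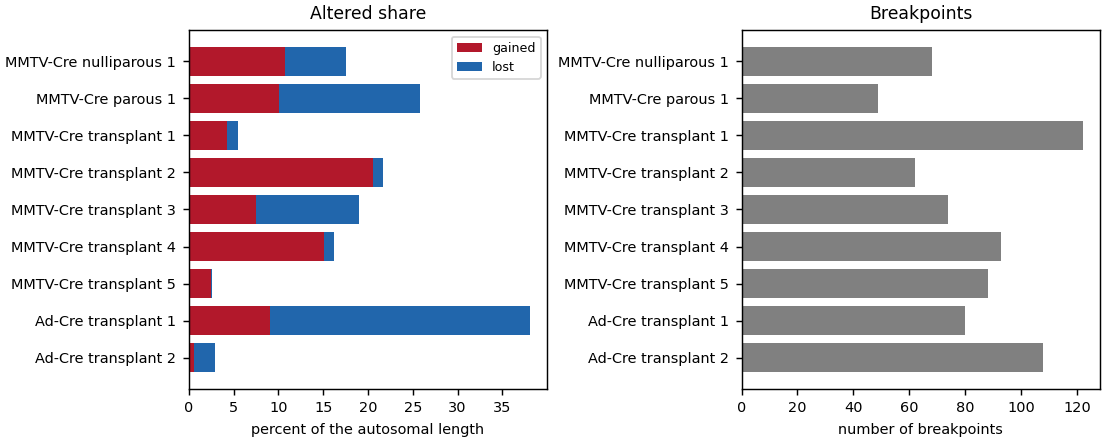
Percent of the autosomal length gained (red) or lost (blue) and number of breakpoints in each tumour, bars from 0. The altered share is highest in Ad-Cre transplant 1, 38.1%, while MMTV-Cre transplant 1 has 122 breakpoints at an altered share of 5.47%.

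Whether the 2 ways of delivering Cre gave different genomes was tested window by window. Between Ad-Cre and MMTV-Cre, limma called 0 of 23357 windows. At an unadjusted p under 0.05 there were 556, fewer than the 1 in 20 that chance alone gives. For whole autosomes the smallest adjusted exact permutation p was 0.704, but 36 groupings could pass the threshold only if most autosomes sat at the smallest p, so this test could hardly call one. In simulated data this comparison recovered 35% of windows shifted by 0.5 and 96% of those shifted by 1. Limma called 1 window without MMTV-Cre transplant 5 and 3 without Ad-Cre transplant 1, which leaves a single Ad-Cre tumour assumed to vary like the others. Within the hybridisation day that held both models it called 162 windows, 38 higher and 124 lower in Ad-Cre, but there the MMTV-Cre tumours were the nulliparous and the parous one, so delivery and transplantation are not separate.

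Between transplanted and other MMTV-Cre tumours, 1 window differed, on chromosome 14 from 18200001 to 18300000. Its mean was -0.17 in the transplants and -1.03 in the other tumours, a difference of 0.86 (limma adjusted p = 0.0353). An unadjusted limma p under 0.05 was seen in 1204 of 23357 windows, about the 1 in 20 that chance alone gives. For whole autosomes the smallest adjusted exact permutation p was 0.724, but 21 groupings could pass the threshold only with every autosome at the smallest p, so this test says nothing on whether autosomes differed. The count was 84 without the nulliparous tumour and 20 without the parous tumour, each a contrast with a single tumour whose spread is taken from the transplants. It was 30 without the library labelled MMTV-Cre transplant 2 and 0 without any of the other transplants. The 2 groups were hybridised on different days, so day and transplantation cannot be told apart.

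The fixed gene lists were placed by chromosome. Each gene took the mean of its whole chromosome, so the test could not register focal events. Met entered at -0.02 and Yap1, Birc2 and Birc3 at -0.04, whatever the amplifications on chromosomes 6 and 9 hold. A list that did not pass therefore says nothing on the copy number of its single genes. Of the 31 amplified oncogenes, 5 sit on the gained chromosomes (Pik3ca, Sox2, Mcl1, Cdk6 and Myc) and 6 on the lost ones (Ccnd1, Ccne1, Fgfr2, Igf1r, Gab2 and Aurka), and their mean chromosome value was 0.00 (adjusted p = 0.874). Of the 30 tumour suppressors 4 sit on gained chromosomes, Fbxw7, Brca2, Chek2 and Kmt2c, and 2 on lost ones, Palb2 and Tsc1 (mean 0.03, adjusted p = 0.535). The mammary lineage list has 6 members on gained chromosomes, among them Krt5, Krt8 and Krt18 on chromosome 15, and 4 on lost ones (mean 0.02, adjusted p = 0.818). The RB and E2F list (mean 0.01, adjusted p = 0.858) did not pass the test. Nor did p53 pathway, homologous recombination, EMT and claudin-low and mitochondrial translation (each mean -0.01, adjusted p = 0.818), or mitosis and centrosome and RAS and PI3K signalling (each mean 0.02, adjusted p = 0.818). Antigen receptor loci passed (mean -0.05, adjusted p = 0.0011), but their 532 symbols lie on 4 chromosomes and are not independent draws, so this p carries little weight.

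Chromosome X was variable, with a mean of -0.17 ± 0.36 (SD, n = 9; exact p = 0.199) and a range from -0.75 in the library labelled MMTV-Cre transplant 2 to 0.26 in MMTV-Cre transplant 4.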

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

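In this part the tests of hybridisation day, recipient DNA, few tumour cells, wrong label, fixed offset and centring were chosen after the results had been seen, and the test of reference signal was set before the signals were looked at. Among the 5 MMTV-Cre transplants, 25 measures were checked for a tumour far from the others, and chance marks about 1 in 20. MMTV-Cre transplant 3 stood apart with 11.5% of its autosomal length lost, against 0.154% to 1.26% in the others, and with -0.39 on chromosome 2, against -0.11 to -0.05. The library labelled MMTV-Cre transplant 2 stood apart with 0.40 on chromosome 5, against 0.08 to 0.16, and with 0.41 on chromosome 19, against -0.04 to 0.08.

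The chromosome 11 run, low in 8 tumours, was level with its flanks in the library labelled MMTV-Cre transplant 2. Few tumour cells would damp its other changes too, yet its highest chromosome median was 0.75, on chromosome 3, which argues against that; a focal loss of -2.31 on chromosome 4, considered first, points the same way but could be inherited. A wrong label cannot be told apart from the mixed strain background: its probe residuals correlated at most 0.699 with another transplanted tumour, against 0.817 to 0.871 among the other 6, and 0.697 with the nulliparous tumour, within the 0.463 to 0.702 of pairs with a tumour not transplanted. The short loci went both ways. Its tumour signal was 0.907 and 0.589 of the autosomal median at loci on chromosomes 6 (from 41013611) and 17, where the nulliparous tumour had 0.0408 and 0.0428. At loci on chromosomes 11, 4 and 12 (from 104951069) it had 0.0338, 0.0457 and 0.124, below every other transplanted tumour. The nulliparous tumour had 0.0536, 0.0692 and 0.124 there. At the remaining loci, on chromosomes 12 and 6, it had 0.229 and 0.627 and the nulliparous tumour 0.0813 and 0.445. Unlike this library, both tumours not transplanted were low at the run. A tumour that kept this part of Trp53 was not tested and stays open.

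Short loci on chromosomes 4, 6, 11, 12 and 17 had high ratios in several tumours. A sequence scarce in the reference pool is a candidate explanation: the high probes of the 7 loci had a median reference signal of 0.0519 of the autosomal median, while amplifications picked the same way had 0.922 to 1.04. Hybridisation day is argued against, since at 6 of the 7 loci a single day held both a tumour at 1 or more and one under 0.25. Recipient DNA in the transplants may add to it: over the 7 transplanted tumours the signal left in the chromosome 11 run had r = -0.26 with the tumour signal at the loci (exact permutation p = 0.495), which leaves it open. The design gives no strain per tumour, so inherited differences between strains were not tested.

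Chromosomes 3, 5, 7 and 15 had one sign in 9 of 9 tumours. A fixed array or dye offset would give every array about the same value, but the array nearest 0 held at most 0.287 of a chromosome's mean, under a bound of 0.33 that was set after seeing the values. For the calls, centring is argued against as well, since with the arrays centred on the mode the largest adjusted exact p of the 4 was 0.0297. The count of tumours does depend on centring: Ad-Cre transplant 2 had 0.0116 and 0.00971 on chromosomes 3 and 5, below its mode of 0.015. With the mode, those chromosomes therefore no longer have one sign in 9 of 9. GC content was not tested, because no genome was given, and dye swaps were not made, so a technical part of these means remains possible. No biological explanation was tested, since the series holds no group of tumours labelled as keeping Rb and p53.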

How the results depend on the processing

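The size limits on segments were chosen after seeing the data; the other settings were planned. The chromosome 11 run kept its direction under 15 alternatives, from -1.40 to -1.19 with a tumour left out, and chromosomes 3, 5, 7 and 15 kept their direction under 18 alternatives and their call under 16. With the 7 MMTV-Cre tumours or the 5 MMTV-Cre transplants alone, exact tests called 0 gained and 0 lost autosomes, although the means stayed of like size (chromosome 3 at 0.29 and 0.33, 5 at 0.19 and 0.19, 15 at 0.20 and 0.19, 7 at -0.14 and -0.10); fewer samples raise the smallest exact p to 0.0156 and 0.0625. The transplants alone gave 2211 gained and 2081 lost windows. A minimum mean of 0.25 left 1116 gained and 296 lost. The normexp correction gave a mean altered share of 27.9%, 2844 lost windows, 0 transplant windows by limma (853 at unadjusted p under 0.05), 53 breakpoints, 328 recurrent gained windows, and 79 gained and 13 lost high-level segments. Centring on the mode gave 2627 gained windows and 25 recurrent gains. No filter on dim spots gave 28 transplant windows, 140 breakpoints and 412 gained high-level segments. The strict filter gave 0 transplant windows (1153 unadjusted) and 22 recurrent gains, and the median per window 0 (853 unadjusted). None of these unadjusted counts exceeded the 1 in 20 windows that chance alone gives. Penalty factor 5 gave 131 breakpoints and 107 and 7 recurrent gained and lost windows; factor 20 gave 56.4 breakpoints and 133 recurrent gains. Bins of 10 probes gave 19 recurrent gains and 107 gained high-level segments. A threshold of 0.15 gave a mean altered share of 34.4%, a transplant difference of -11.3 (exact p = 0.0476), and 3 and 55 recurrent gained and lost windows; 0.4 gave 3.94% and a reversed difference of 3.71. A high-level threshold of 1.5 gave 119 gained and 9 lost segments. Day as a random block gave 7110 lost windows, with a negative day correlation of -0.18; within the day holding both models limma called 162 windows between Ad-Cre and MMTV-Cre, and the altered share difference reversed to -1.16. Segments of at least 1 Mb gave 18 recurrent gains and 0 losses, and of at least 300 kb 40 and 0 high-level segments. Leaving out each tumour in turn gave 3 to 5 gained and 1 to 3 lost autosomes, chromosome 2 at -0.16 to -0.11, 0 to 84 transplant windows, 0 to 3 Ad-Cre windows, 5 to 42 recurrent gains, and altered share differences of -12.6 to 22.6 for Ad-Cre and -12.8 to -4.56 for transplants; where this leaves 1 tumour in a group, limma takes its spread from the others. Apart from the subsets, whose size limits the test, the cause was not tested. No paired analysis was possible because replicate numbers only follow the order of deposit. The GC correction was not run. Dim reference spots limit the short loci, where the reference signal is near background.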

Other observations

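In this part the relations across tumours, the omission of short loci and the subsets of tumours in them were chosen after the values had been seen. With the segments in short shared loci left out, chromosome 4 of MMTV-Cre transplant 4 stepped 38 times, with segment values between -0.66 and 0.40 and 27 turns of direction out of 37 possible. Chromosome 8 of MMTV-Cre transplant 1 turned 43 times out of 60, with segments between -0.44 and 1.92. No test separated these from other forms of crowding.

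The median over the 7 short loci of the tumour signal, as a share of the autosomal median, was 0.07 in the nulliparous and 0.07 in the parous tumour. It was 0.39, 0.39, 0.38 and 0.52 in MMTV-Cre transplants 1, 3, 4 and 5, 0.45 and 0.72 in Ad-Cre transplants 1 and 2, and 0.23 in the library labelled MMTV-Cre transplant 2. In that library the loci ran from 0.0338 on chromosome 11 to 0.907 on chromosome 6, so 0.23 is not a level they share. The relations below that include this library use that median. If recipient DNA were in the transplants, it could raise this signal together with the signal left in the chromosome 11 run. Over the 7 transplanted tumours Pearson's r was -0.26 (exact permutation p = 0.495, adjusted 0.675) and Spearman's rho -0.04 (exact p = 0.963, adjusted 0.963), and r was 0.77 without the 2 tumours farthest on the signal at the loci. Without the library labelled MMTV-Cre transplant 2, a choice made after its values were seen, r was 0.90 (exact p = 0.0222, adjusted 0.111) and rho 0.54 (exact p = 0.297, adjusted 0.598) over 6 tumours. That r fell to -0.14 without the 2 farthest, so it rests on them. Over all 9 tumours r was 0.15 (exact p = 0.675, adjusted 0.675) and rho 0.35 (exact p = 0.359, adjusted 0.598), with r = -0.16 without the 2 farthest. The sign thus changes with the tumours included and the hypothesis stays open.

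A second relation, of altered share on the log2 ratio of the chromosome 11 run minus its flanks, did not pass a test. A deeper run has a lower value, so a negative r means a larger altered share with a deeper run. Over 9 tumours r was -0.19 (exact permutation p = 0.619, adjusted 0.675) and rho -0.22 (exact p = 0.581, adjusted 0.726), and r was -0.38 without the 2 farthest. Without the library labelled MMTV-Cre transplant 2, r was -0.55 (exact p = 0.162, adjusted 0.404) and rho -0.45 (exact p = 0.267, adjusted 0.598) over 8 tumours, and 0.19 without the 2 farthest. In all, 2 relations were computed in 5 sets of tumours, and 0 had an adjusted exact p under 0.05, with 1 under 0.05 unadjusted. Hybridisation days are too small for a value within each: the days held 2, 3 and 4 tumours.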
